A study of Mus musculus with 18 samples.

How the data were processed

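Total RNA from the dorsal telencephalon of 18 mouse embryos at E13.5 was measured on Affymetrix whole-transcript exon arrays, 1 array per embryo: 8 wildtype, 6 heterozygous and 4 homozygous for an Insm1 knockout. Per the labels, RNA was extracted with TRIZOL, ribosomal RNA was reduced, and sense-strand target was made, labelled with biotin and hybridized. The deposited values are log2 signals per transcript-level probe set, made per the submitters' processing notes with RMA (background correction, quantile normalization and summary of probes; no version given) in Affymetrix Expression Console 1.1. The base of the logarithm was checked on the values: the lowest of the array maxima was 11.3, above 11.1, the natural log of the 16-bit scanner maximum. Values ran from -0.52 to 11.7, and array medians from 1.55 to 1.64.

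The table held 23238 probe sets. The main tests used the 16661 whose identifiers fall in the numbering range of the platform's probe table; the other 6577 have lower identifiers, are absent from that table and cannot be assigned to a gene. This choice was made after the table was seen and before any test, and the tests were repeated on the whole table as an alternative. Of the 16661, 14939 had 1 gene symbol, 989 several and 733 none. Gene identifiers were matched to a GRCm38.p6 gene table for chromosomes and lengths (14884 of 14939 matched). For gene lists, 1 probe set per gene was taken, that with the highest mean over all arrays, giving 14807 genes, of which 131 had more than 1 probe set.

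Groups follow the genotype in the labels. A linear model with a mean per genotype was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over the 16661 probe sets, with a threshold of 0.05. The contrasts were homozygous against wildtype, heterozygous against wildtype, homozygous against heterozygous, and heterozygous against the midpoint of the other genotypes. A separate fit gave the slope per mutant allele. No low-level filter, covariate or block was used. Insm1 was also tested by exact permutation of the group labels, two-sided by doubling the smaller tail. The labels do not say that embryos came from separate litters, and replicate numbers are not said to pair embryos. The number of arrays, above all the 4 homozygous ones, limits the precision.

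The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Insm1; the 12 higher and 12 lower probe sets with 1 symbol and the largest log2 change among those that passed in homozygous against wildtype; up to 5 per direction in the smaller comparisons, or the 2 with the smallest unadjusted p where none passed; and the 3 members of each list with the smallest unadjusted p. Genes named beyond the rule are members of the fixed lists or are marked as chosen after their values were seen.

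The 17 tested lists were basal progenitors, apical progenitors, cortical neurons, Cajal-Retzius neurons, ventral telencephalon and interneurons, cortical hem and choroid plexus, meninges and mesenchyme, erythroid cells, endothelium and pericytes, microglia and macrophages, S phase, G2 and M phase, Notch pathway, neurosecretory genes, p53 targets and apoptosis, immediate early and heat shock genes, and hypoxia response. Each was tested with camera in limma, which compares a list with all other genes, with a preset correlation between genes of 0.01, adjusted over the 17 lists. Repeats used a correlation estimated from the data and the rotation test fry, which asks whether the members move one way on balance. Y-linked genes were only checked: Eif2s3y lay at 0.27 to 0.66 or at 4.46 to 5.12, and both levels occurred in each genotype. Among homozygous embryos only replicate 4 had the high level (5.12). Wildtype replicates 1, 2, 5, 6 and 7 and heterozygous replicates 3, 4 and 6 had it too. The genotypes were therefore not balanced for this marker of male embryos.

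The processing was varied with a trended robust prior, a further quantile normalization, median centring, array weights, leaving out the dimmest 1 of every 3 probe sets, fitting only the groups compared, a block by replicate number, 1 probe set per gene, the mean of the ventral or the erythroid list as covariate, stricter and looser thresholds, and leaving out each array. Added after the data were seen were the whole table, covariates for the 75th percentile of each array, Eif2s3y and the hypoxia list, and the removal of heterozygous replicate 6 and homozygous replicate 2, which lay farthest along the first principal component (33.5% of the variance).

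The procedure was tested on simulated data with the same group sizes. For homozygous against wildtype it recovered 13 of 67 genes with a log2 change of 0.25, 57 of 67 with 0.5 and 64 of 66 with 1, with 9 false among 143 calls. A simulated heterozygous group without changes gave 0 calls, and a list shifted by -0.3 was called with 0 of 16 other lists. The simulated genes varied independently, so correlation between genes, to which the list test is sensitive, was not covered.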

Results

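Transcript levels were measured in the dorsal telencephalon, the part of the embryonic forebrain that forms the neocortex, of 18 mouse embryos at E13.5 (embryonic day). The embryos differed in Insm1, which encodes a zinc finger transcription factor of developing neurons and endocrine cells. There were 8 wildtype embryos, 6 heterozygous embryos with 1 mutant allele and 4 homozygous embryos with 2. The stated purpose was a search for genes under the control of Insm1. Each embryo gave 1 whole-transcript array, read out as a log2 value per transcript-level probe set, so that a difference of 1 is a 2-fold change. The 75th percentile of an array lay between 4.67 and 4.87 in the wildtype arrays and between 4.67 and 4.75 in the homozygous arrays. Heterozygous replicate 6 lay lower, at 4.50. The labels do not say whether embryos of 1 genotype came from separate litters, so the p-values measure the spread between these embryos.

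The Insm1 level was 5.34 ± 0.34 (SD, n = 8) in wildtype embryos, 4.77 ± 0.39 (SD, n = 6) in heterozygous embryos and 3.31 ± 0.34 (SD, n = 4) in homozygous embryos. The homozygous value was 24.5% of the wildtype value on the linear scale, a log2 change of -2.03 (SE 0.20, limma adjusted p = 3.8e-05). All 4 homozygous embryos lay below every wildtype and every heterozygous embryo, and the two-sided exact permutation test gave p = 0.00404 against wildtype and p = 0.00952 against heterozygous, each the smallest value that its design can give. In heterozygous embryos Insm1 was at 67.2% of wildtype, a log2 difference of -0.57 (SE 0.18). That difference gave p = 0.0107 in the exact permutation test of Insm1 alone and an adjusted p = 0.64 in limma over all probe sets. Insm1 was measured by 1 probe set, and whether its probes lie within the deleted part of the gene is not given in the sources used here.

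**Figure D1:**
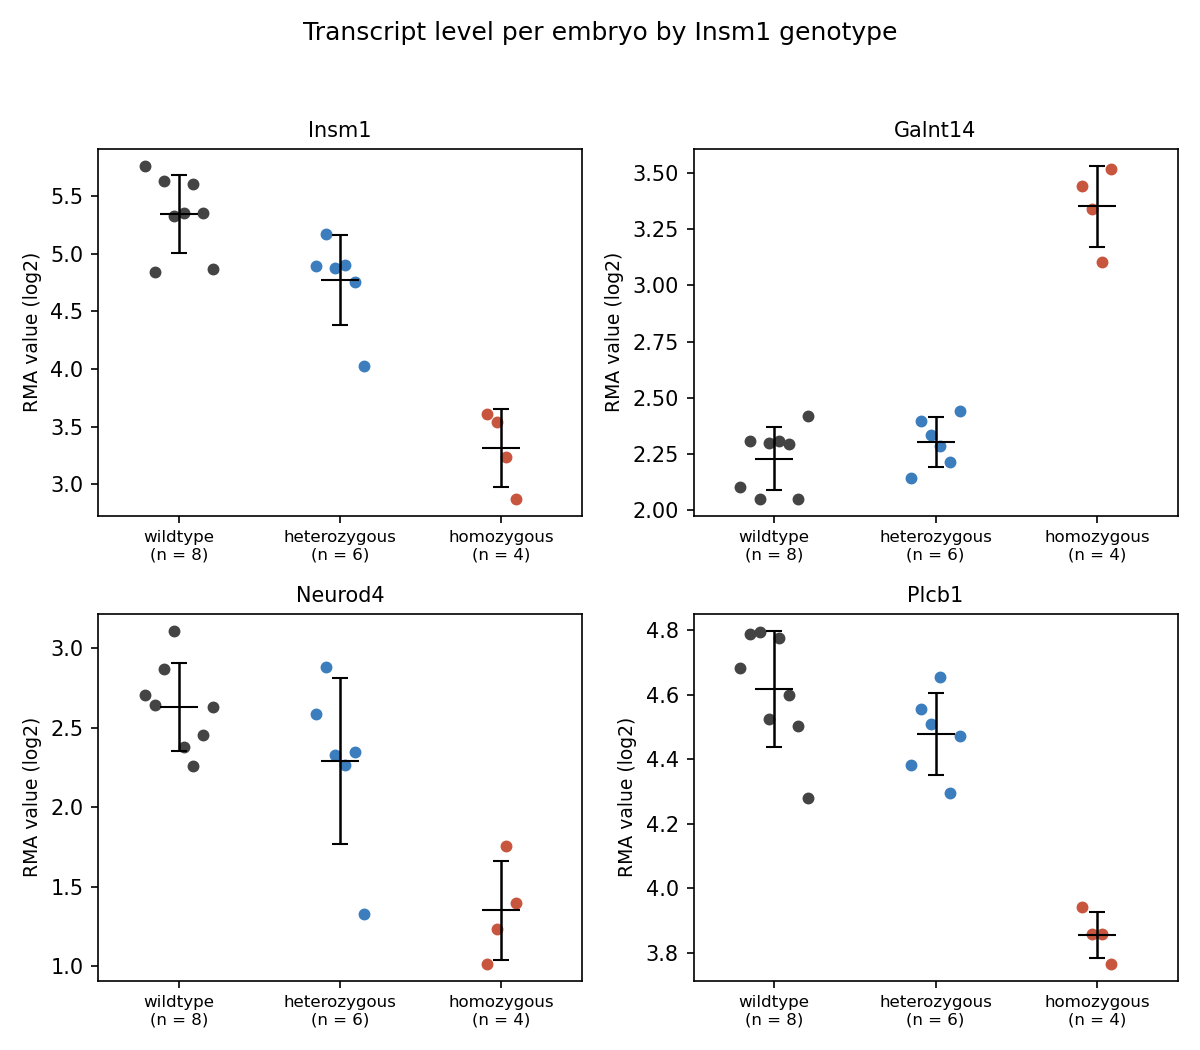
RMA log2 values of Insm1, Galnt14, Neurod4 and Plcb1 (vertical axes) in each embryo by genotype (horizontal axes), with every point 1 embryo, the wide bar the group mean and the error bar 1 SD; each panel has its own vertical range, which does not start at 0. The 4 homozygous embryos lie between 3.10 and 3.52 for Galnt14, and the other 14 embryos between 2.05 and 2.44.

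The comparison of homozygous with wildtype embryos asked which transcripts changed when both alleles were lost. Neurod4, a proneural basic helix-loop-helix factor, fell by 1.28 on the log2 scale (SE 0.21, limma adjusted p = 0.00573), from 2.63 ± 0.28 (SD, n = 8) to 1.35 ± 0.31 (SD, n = 4), which is near the floor of the arrays, so that the size of the fall is uncertain. Nhlh1, a related factor of newly formed neurons, fell by 0.69 (SE 0.11). The axonal adhesion molecule Cntn2 fell by 0.72 (SE 0.15) and the transmembrane semaphorin Sema6d by 0.83 (SE 0.11). The zinc finger factor St18 fell by 0.73 (SE 0.09), and Plcb1, a phospholipase C, fell by 0.76 (SE 0.09, limma adjusted p = 0.000256).

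The other lower genes among the 12 with the largest change were Sh3bgrl2 (-0.87), Akna (-0.76), Clmp (-0.75), the acid-sensing channel gene Asic1 (-0.72) and Chst15 (-0.69), a sulfotransferase that acts on chondroitin sulfate. In each of these genes and in those of the preceding paragraph, the 4 homozygous embryos lay below all 8 wildtype embryos. Some further lower genes were chosen for mention after their values were seen: the axon guidance receptor gene Robo2 fell by 0.67 (SE 0.07), the adhesion molecule gene L1cam by 0.69 (SE 0.10), Dscam by 0.57 (SE 0.10) and Celsr3 by 0.62 (SE 0.12). The call of Celsr3 ended after quantile normalization (-0.55, adjusted p = 0.051) and with the hypoxia list as a covariate (-0.54, adjusted p = 0.056). The calls of Clmp and Cntn2 ended when the 75th percentile of each array was a covariate (adjusted p = 0.055 and 0.063), with changes of -0.56 and -0.59. They also ended, like that of Asic1, with the ventral list (adjusted p = 0.106, 0.082 and 0.057) and with the hypoxia list as a covariate (adjusted p = 0.127, 0.084 and 0.068), with changes of -0.69, -0.71 and -0.69, and of -0.59, -0.55 and -0.64.

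Among the higher genes, Galnt14, an enzyme that starts mucin-type O-glycosylation, had the largest rise, 2.18-fold (log2 change 1.12, SE 0.09, limma adjusted p = 1.15e-06), from 2.23 ± 0.14 (SD, n = 8) to 3.35 ± 0.18 (SD, n = 4). The cyclin-dependent kinase inhibitor gene Cdkn1c rose by 0.71 (SE 0.14), from 5.55 to 6.27. Tacr1, the receptor of substance P, rose by 0.54 (SE 0.08), the ephrin gene Efna1 by 0.37 (SE 0.07) and the metallothionein gene Mt3 by 0.38 (SE 0.08); Tacr1 (wildtype mean 1.07) and Efna1 (1.36) lay near the floor of the arrays. Mcee (0.61), Mrpl54 (0.50) and Gpx8 (0.39) also rose. In these 3 genes and in Mt3 the homozygous and wildtype embryos overlapped, and their calls ended with the ventral list as a covariate (adjusted p = 0.061, 0.053, 0.057 and 0.074), with changes of 0.64, 0.52, 0.43 and 0.36. With the hypoxia list as a covariate the calls of Mcee, Gpx8 and Mt3 ended (adjusted p = 0.084, 0.138 and 0.062), with changes of 0.61, 0.32 and 0.38, and that of Mrpl54 held (0.58, adjusted p = 0.0191). The olfactory receptor gene Olfr130 rose by 0.78 (SE 0.13) from a wildtype mean of 0.21, which is at the floor of the arrays. Its homozygous mean of 1.00 included 1 embryo at 1.56. Of the 10 higher probe sets, 3 had a mean under 1.5 over all arrays: Olfr130, Tacr1 and Efna1.

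**Figure D2:**
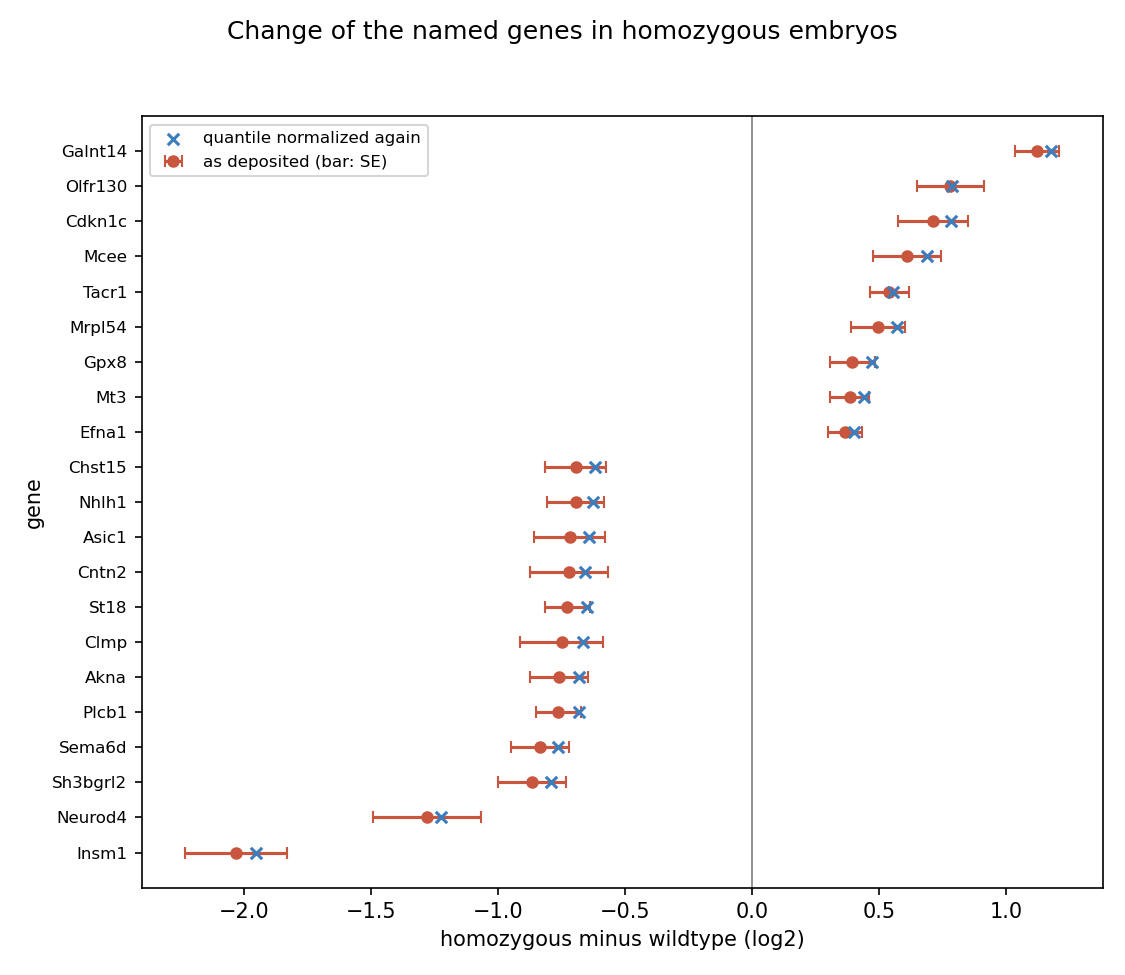
Log2 change, homozygous minus wildtype (horizontal axis), of the 9 higher and 12 lower genes that the rule fixed beforehand names (vertical axis); circles are the values as deposited with bars of 1 SE, and crosses are the values after a further quantile normalization of the arrays. The direction of each of these genes is the same in both, and the changes run from -2.03 for Insm1 to 1.12 for Galnt14.

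In all, 94 of 16661 probe sets changed in homozygous embryos, 84 lower and 10 higher, with a median absolute log2 change of 0.46. At an unadjusted p under 0.05 there were 2546, against 833.05 expected by chance. The homozygous and wildtype embryos did not overlap in 81 of the 94, as follows in large part from their selection for this difference; the share was 2.48% of all those tested, against 0.404% expected by chance. The split into higher and lower depended on the scale of the arrays: a further quantile normalization called 84 higher and 74 lower, and centring each array on its median called 75 higher and 67 lower. All 94 kept their direction under quantile normalization, and 38 of them, 32 lower and 6 higher, were called under both rescalings and with each of 3 covariates (75th percentile, ventral list, hypoxia list). Single embryos also moved the count: it was 36 without homozygous replicate 2 and 37 without homozygous replicate 3. It rose to 394 without homozygous replicate 1, 369 without heterozygous replicate 6 and 188 without wildtype replicate 7, and was 62 and 60 without wildtype replicates 1 and 3.

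Genes of cortical neurons were lower as a group in homozygous embryos. All 20 measured members of the list had a lower mean, under each scaling as well, with a median log2 change of -0.31. Of them 6 fell over all genes tested (Ina, Elavl2, Elavl3, Map2, Cntn2 and Neurod1), and 15 fell when adjusted over the list alone. The neuronal filament gene Ina fell by 0.57 (SE 0.09), and the neuronal RNA-binding protein genes Elavl3 and Elavl2 fell by 0.43 (SE 0.09) and 0.33 (SE 0.06); the call of Elavl3 ended after quantile normalization (-0.38, adjusted p = 0.052) and median centring (-0.36, adjusted p = 0.074). Both calls ended with the ventral list (adjusted p = 0.069 and 0.063) and with the hypoxia list as a covariate (adjusted p = 0.071 and 0.069), with changes of -0.40 and -0.31, and of -0.40 and -0.30. The call of Map2 (-0.30) ended after quantile normalization (-0.25, adjusted p = 0.076), after median centring (-0.24, adjusted p = 0.125) and with the hypoxia list (-0.32, adjusted p = 0.051). That of Neurod1 (-0.69) ended with the ventral list (-0.63, adjusted p = 0.106) and with the hypoxia list (-0.57, adjusted p = 0.13). Tbr1 (-0.20) and Fezf2 (-0.08), transcription factors of deep layer neurons, did not pass the test over all genes. The list shifted in camera with a preset correlation (adjusted p = 7.08e-14) and in fry (adjusted p = 0.00089), and the call was lost with an adjusted p = 0.077 with an estimated correlation. The mean of the list was 6.20 ± 0.13 (SD, n = 8) in wildtype, 6.07 ± 0.12 (SD, n = 6) in heterozygous and 5.84 ± 0.04 (SD, n = 4) in homozygous embryos.

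Markers of Cajal-Retzius neurons, the early neurons of the cortical surface, were lower too. Of 10 measured members 9 had a lower mean, with a median of -0.34; only Ebf3 fell over all genes tested (-0.46, SE 0.08), and 7 fell when adjusted over the list alone. Reln, their best known product, had a difference of -0.37 (SE 0.20, adjusted p = 0.39). The list shifted in camera (adjusted p = 3.68e-05), and this call held with an estimated correlation (adjusted p = 0.0294). Without homozygous replicate 2 and heterozygous replicate 6 the list passed with the preset correlation (median -0.29, adjusted p = 0.00023), with adjusted p = 0.104 with an estimated correlation.

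Genes of the basal progenitor list moved both ways. Neurod4, Nhlh1 and Elavl4 (-0.44, SE 0.07) fell over all genes tested, while adjusted over the list alone 5 of 13 fell and 2 rose. Nhlh1 is a factor of newly formed neurons, and Elavl4 is related to Elavl2 and Elavl3 of the cortical neuron list. Their fall therefore does not measure basal progenitors alone. Eomes, the T-box factor of these cells, differed by -0.34 (SE 0.08, adjusted p = 0.061). The Notch ligand gene Dll3 differed by 0.29 (SE 0.09, adjusted p = 0.12) and was called higher after quantile normalization (adjusted p = 0.0167). The list as a whole did not pass camera (median -0.23, adjusted p = 0.069, and adjusted p = 0.592 with an estimated correlation), but passed with the preset correlation after median centring (median -0.16, adjusted p = 0.0166). It did not pass camera after quantile normalization (median -0.17, adjusted p = 0.085). With the 75th percentile, ventral and hypoxia covariates its medians were -0.14, -0.20 and -0.12 (camera adjusted p = 0.217, 0.137 and 0.308).

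**Figure D3:**
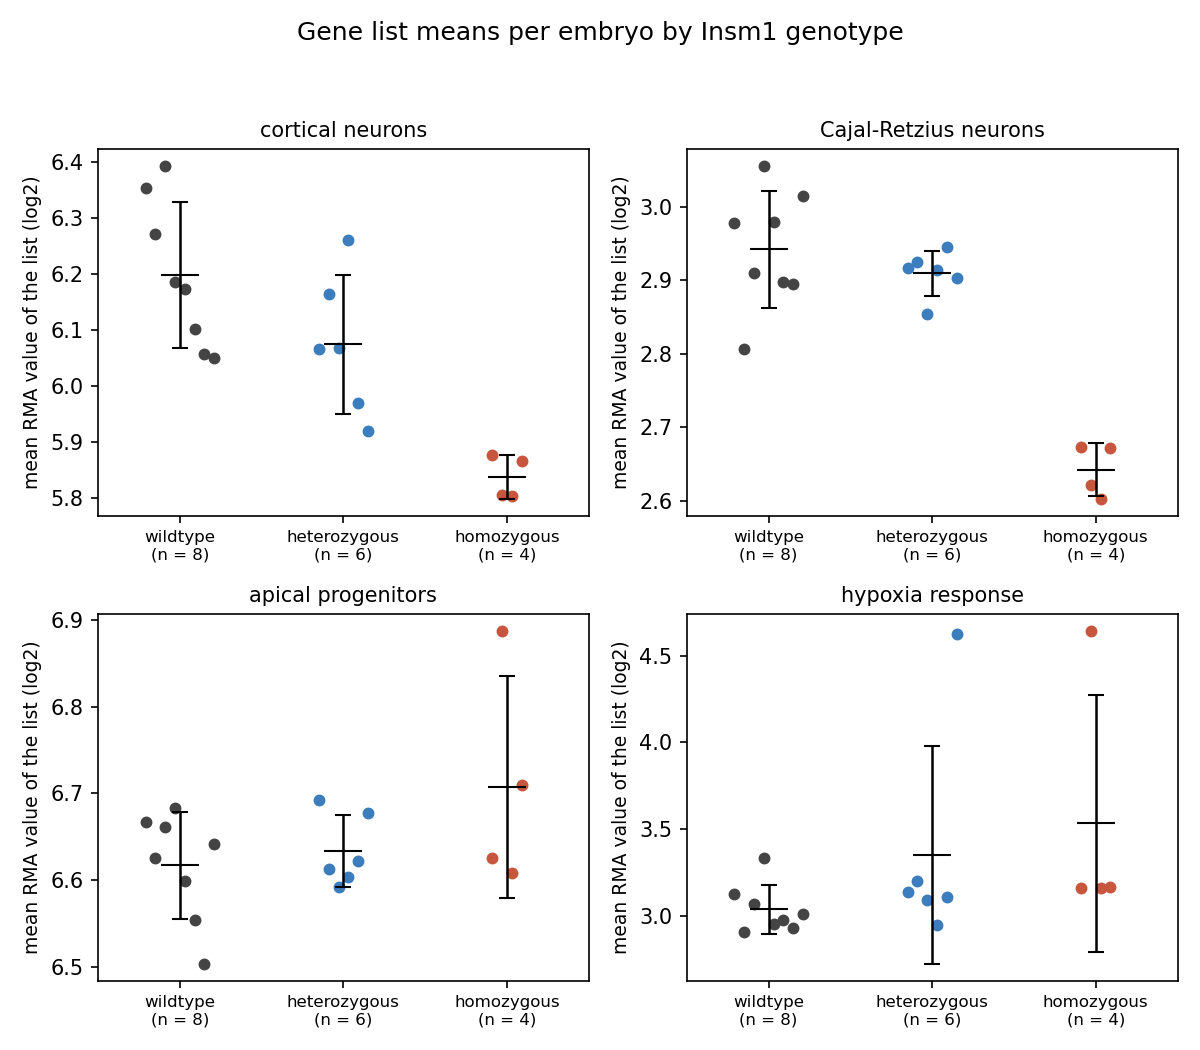
Mean RMA log2 value of each gene list (vertical axes) in each embryo by genotype (horizontal axes), with every point 1 embryo, the wide bar the group mean and the error bar 1 SD; the vertical ranges differ and do not start at 0. For the hypoxia list, homozygous replicate 2 (4.64) and heterozygous replicate 6 (4.62) lie above all other embryos.

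A pair of lists was higher in homozygous embryos in camera. Apical progenitor genes had a median of 0.07 (adjusted p = 0.0235), and none of 16 changed over all genes tested, against 1 higher and 1 lower adjusted over the list alone. The call was lost with an adjusted p = 0.351 with an estimated correlation. The closest to the threshold were Veph1 (0.32, SE 0.07, adjusted p = 0.0501), which passed after quantile normalization (0.34, adjusted p = 0.0172) and median centring (0.38, adjusted p = 0.0193), and the LIM homeobox gene Lhx2 (-0.21, SE 0.05, adjusted p = 0.061), while the glial lipid-binding protein gene Fabp7 differed by 0.44 (SE 0.16). Hypoxia response genes had a median of 0.53 (adjusted p = 0.00106, but adjusted p = 0.351 with an estimated correlation), with all 8 measured members higher on average, and none passing over all genes or adjusted over the list alone. Bnip3 differed by 0.80 (SE 0.45), the glucose transporter gene Slc2a1 by 0.69 (SE 0.38) and Ankrd37 by 0.20 (SE 0.11). The hypoxia list stood at 4.64 in homozygous replicate 2 and between 3.16 and 3.17 in the other homozygous embryos. Without that array and heterozygous replicate 6, its median was 0.08 (adjusted p = 0.0376, and adjusted p = 0.461 with an estimated correlation), and the apical list had a median of 0.01 (adjusted p = 0.23).

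The remaining lists did not pass camera in homozygous against wildtype embryos, although the Notch pathway passed after quantile normalization (median 0.06, adjusted p = 0.0293) and the G2 and M phase list with the hypoxia list as a covariate (median -0.12, adjusted p = 0.0193, and adjusted p = 0.749 with an estimated correlation). Of cell cycle genes, the G2 and M phase list had a median of -0.09 (adjusted p = 0.09) and the S phase list of -0.06 (adjusted p = 0.62); Bub1b differed by -0.24 (SE 0.07), Cenpe by -0.33 (SE 0.10) and Tyms by -0.31 (SE 0.11). The Notch pathway had a median of 0.02 (adjusted p = 0.09), with Hes5 at a difference of 0.43 (SE 0.18) and Mfng at -0.32 (SE 0.15). The difference of Hes5 rested largely on homozygous replicate 2 (8.60). The nearest homozygous embryo was at 7.33, and the wildtype embryos at 7.06 to 7.24. The Notch list did not pass camera after median centring (adjusted p = 0.153) or with the 75th percentile covariate (adjusted p = 0.217). Neurosecretory genes had a median of -0.10 (camera adjusted p = 0.16). Insm1 is known as a regulator of such genes in endocrine cells, but the median level of the list was low (1.71), which limits what it can show. Scg3 differed by -0.52 (SE 0.12, adjusted p = 0.0501) and passed after quantile normalization (adjusted p = 0.0185), and Chga differed by -0.49 (SE 0.19). The p53 target list had a median of -0.10 (adjusted p = 0.15), and Zmat3 differed by -0.23 (SE 0.09). Immediate early and heat shock genes had a median of -0.04 while the test pointed up (adjusted p = 0.86), and Hsph1 differed by -0.20 (SE 0.06). No member of these lists passed over all genes; adjusted over the list alone, 2 members of the G2 and M phase list and 1 each of the neurosecretory and immediate early lists were lower.

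Lists for tissue that could be carried along in the dissection did not pass either. Most had low median levels, which limits what they can show. These were 1.88 for ventral telencephalon, 1.52 for meninges, 1.84 for erythroid cells, 1.71 for endothelium and 0.92 for microglia, against 3.49 for cortical hem. Ventral telencephalon and interneuron genes had a median of -0.15 (adjusted p = 0.54), with Gad2 at a difference of -0.28 (SE 0.17). Cortical hem and choroid plexus genes had a median of -0.03 while the test pointed up (adjusted p = 0.68), and Ttr, the main choroid plexus transcript, varied within every genotype (SD 1.62 in wildtype). The medians were 0.02 for 5 erythroid genes (adjusted p = 0.15), where Hbb-y differed by 0.23 (SE 0.11), and -0.02 for endothelium and pericytes (adjusted p = 0.62), where Cdh5 differed by -0.45 (SE 0.12, adjusted p = 0.082). Meninges and mesenchyme (adjusted p = 0.55) and microglia and macrophages (adjusted p = 0.86) had medians of -0.00, with tests that pointed up. No member passed over all genes, and adjusted over the list alone 1 endothelial and 1 microglial gene were lower.

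Heterozygous embryos were compared with wildtype embryos to ask what the loss of 1 allele did. No gene passed the test: limma called 0 of 16661 probe sets, the smallest adjusted p was 0.41, and 1245 probe sets had an unadjusted p under 0.05. The 2 genes with the smallest unadjusted p in each direction were E2f8, an atypical E2F factor of the cell cycle (-0.41), 1700025G04Rik (-0.43), and, near the floor of the arrays, Dkk4 (0.24) and Nxnl1 (0.27). Of the 94 genes called in homozygous embryos, 91 had a heterozygous difference in the same direction. Both comparisons use the same wildtype arrays. Groups simulated as unchanged against shared controls gave 89.3% in the same direction on average and 97.9% at most, against 96.8% observed. The simulation left the homozygous group unchanged too, unlike these data, so it cannot decide whether the loss of 1 allele had an effect.

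Among gene lists, 3 shifted in camera in heterozygous embryos. Cortical neuron genes had a median of -0.10 (adjusted p = 0.00513, but adjusted p = 0.895 with an estimated correlation), with 19 of 20 lower on average. Hypoxia response genes had a median of 0.29 (adjusted p = 0.00561) and meninges and mesenchyme genes of 0.06 (adjusted p = 0.00848). Both calls were lost, with adjusted p = 0.895 and 0.68 with an estimated correlation. No member of the 3 lists passed over all genes tested or adjusted over the list alone. Without heterozygous replicate 6 and homozygous replicate 2, the cortical neuron list passed (median -0.08, adjusted p = 0.0097, but adjusted p = 0.953 with an estimated correlation), the hypoxia list did not (median 0.04, adjusted p = 0.2) and neither did the meninges list (adjusted p = 0.0513).

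Homozygous embryos were compared with heterozygous embryos to ask what the loss of the remaining allele did. Galnt14 rose by 1.05 (SE 0.09, limma adjusted p = 8.72e-06) and Tacr1, near the floor of the arrays, by 0.59 (SE 0.08). Insm1 fell by 1.46 (SE 0.21), Plcb1 by 0.62 (SE 0.09) and Pde1c, a cyclic nucleotide phosphodiesterase, by 0.50 (SE 0.08). These were the 5 genes that changed, and 1421 had an unadjusted p under 0.05. The count was 21 (9 higher, 12 lower) after quantile normalization, 31 without homozygous replicate 1 and 1 without homozygous replicate 4. In camera, cortical neuron genes (median -0.19, adjusted p = 1.4e-09), Cajal-Retzius genes (median -0.27, adjusted p = 6.56e-06) and ventral telencephalon genes (median -0.15, adjusted p = 0.0321) were lower. The Cajal-Retzius call held with an estimated correlation (adjusted p = 0.0164), and the others were lost (adjusted p = 0.217 and 0.435 with an estimated correlation).

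Across the 3 genotypes as a series of 0, 1 and 2 mutant alleles, 113 genes changed with allele number, 107 falling and 6 rising. Of these, 83 were among the 94 genes above, which come from the same arrays. Insm1 fell by 0.96 per allele (SE 0.11, limma adjusted p = 0.000377), and Galnt14 rose by 0.50 per allele (SE 0.08). Median centring called 74 genes, 28 rising and 46 falling, and the 75th percentile covariate 142, 83 rising and 59 falling, while the count was 33 without homozygous replicate 3 and 255 without wildtype replicate 7.

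Galnt14 was also the single gene whose heterozygous level departed from the midpoint of the other genotypes. Its heterozygous mean was 2.30 ± 0.11 (SD, n = 6), close to wildtype, and lay 0.49 below the midpoint (a departure of -0.49, SE 0.07, limma adjusted p = 0.0285), while Insm1 had a departure of 0.44 (SE 0.17), which did not pass over all genes (adjusted p = 0.81). At an unadjusted p under 0.05 there were 964 such probe sets. Galnt14 no longer passed this test over all genes after quantile normalization, or without any 1 of 10 embryos (wildtype replicates 2, 4, 5 and 6, heterozygous replicates 1 to 5 and homozygous replicate 4).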

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

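Both tests of Galnt14 were chosen only after the result was seen.

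Galnt14 was called as differing between the effects of the first and the second lost allele. Its heterozygous mean departed from the midpoint by -0.49 (SE 0.07, limma adjusted p = 0.0285). The call ended after both rescalings and without some single embryos, and other splits of the embryos do not exclude chance. The low level of Galnt14 in wildtype and heterozygous embryos also limits what this departure can show. A knockout can carry alleles of the strain in which it was made, but Galnt14 lies on chromosome 17 and Insm1 on chromosome 2, which argues against an allele linked to Insm1. Of the 14 wildtype and heterozygous embryos, 0 reached the lowest homozygous value of 3.10 (highest 2.44), but Galnt14 was picked for this separation, so an unlinked allele that segregates among the embryos cannot be told apart from an effect of genotype. A response of Galnt14 to the complete loss of Insm1 may be followed up as a hypothesis, and the labels leave open whether the genotypes came from separate litters.

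Single embryos lay far from the rest of their group in 23 of 279 groups of values tested (8.24%, against 5% by chance). Of these, 11 were in heterozygous replicate 6 and 4 in heterozygous replicate 3. In heterozygous replicate 6 the 75th percentile of the array was 4.50, with the nearest heterozygous array at 4.69. Its Insm1 value was 4.02 (nearest 4.76), Akna 3.75 (nearest 4.28), Mfng 5.17 (nearest 6.02) and Zmat3 3.98 (nearest 4.27), all low. Its values of Jun (6.85, nearest 6.17), Slc2a1 (8.92, nearest 7.13) and Bnip3 (6.52, nearest 4.30) were high. Among list means of that embryo, hypoxia response (4.62, nearest 3.20) and immediate early and heat shock genes (3.68, nearest 3.26) were high, and the Notch pathway (4.78, nearest 4.93) was low.

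Homozygous replicate 2 was high in the hypoxia list (4.64, nearest 3.17) and in Hes5 (8.60, nearest 7.33). In homozygous replicate 3 Olfr130 was high (1.56, nearest 0.83) and Barhl2 low (1.62, nearest 1.92). Heterozygous replicate 3 was low in Dkk4 (0.76, nearest 0.90) and in the means of the meninges list (1.47, nearest 1.58) and the endothelium list (1.75, nearest 1.86), and high in C1qc (1.57, nearest 1.27). Efna1 was low in heterozygous replicate 4 (1.27, nearest 1.41). In wildtype replicate 3 Nxnl1 (0.74, nearest 0.54) and Egr1 (1.26, nearest 0.99) were high, and in wildtype replicate 2 Lhx6 was high (2.42, nearest 2.01).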

How the results depend on the processing

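The alternatives chosen only after the data were seen were the whole table, the 75th percentile, Eif2s3y and hypoxia covariates, and the removal of heterozygous replicate 6 and homozygous replicate 2. Insm1 kept its direction and its side of the threshold under every alternative run, with a change of -2.19 to -1.88 in homozygous and -0.65 to -0.42 in heterozygous embryos, and the count of 0 genes in heterozygous against wildtype stayed at 0 in limma under every alternative. Of 2738 values of genes named by the rule and of shifted lists under alternatives, 2521 stayed on their side of the threshold in the same direction, 177 lost and 37 gained a call, and 3 reversed. The reversed values were of Wnt5a in homozygous against wildtype (-0.08), at 0.00 (0.00322) with quantile normalization, 0.01 (0.0110) with the 75th percentile covariate and 0.02 (0.0151) without homozygous replicate 1; with 1 array left out they ranged from -0.14 to 0.02. Except where fewer genes or arrays were used, the cause was not tested.

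For homozygous against wildtype (94), the count was 158 with quantile normalization and 142 with median centring. It was 146 without the dimmest probe sets and 361 with the replicate block. With covariates it was 57 (ventral), 173 (75th percentile) and 116 (Eif2s3y, with 78 of the 94 among them). It was 37 at a change of at least 0.5 and 383 at an adjusted p under 0.1. It ranged from 36 to 394 with 1 array left out: 62, 60 and 188 without wildtype replicates 1, 3 and 7, 369 without heterozygous replicate 6, and 394, 36 and 37 without homozygous replicates 1, 2 and 3. For homozygous against heterozygous (5), the count was 21 with quantile normalization, 13 with median centring, 3 with array weights, 2 with only these groups, 1 with the replicate block, 12 with the erythroid and 26 with the 75th percentile covariate, and 9 at an adjusted p under 0.1. It ranged from 1 to 31: 9 and 12 without heterozygous replicates 1 and 6, and 31 and 1 without homozygous replicates 1 and 4.

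For allele number (113), the count was 74 with median centring, 536 with the replicate block, 58, 62 and 57 with the ventral, erythroid and hypoxia covariates, 58 over the whole table, 75 without the 2 arrays that stand apart, 3 at a change of at least 0.5 and 456 at an adjusted p under 0.1. It ranged from 33 to 255: 57, 62, 54, 56, 65, 255 and 70 without wildtype replicates 1, 2, 3, 4, 5, 7 and 8, 73, 69 and 234 without heterozygous replicates 3, 5 and 6, and 219, 35, 33 and 45 without homozygous replicates 1, 2, 3 and 4. For departure from the midpoint (1), the count was 0 with the trended robust prior, both rescalings, the replicate block, the ventral and erythroid covariates, the whole table, without the 2 arrays that stand apart and at a change of at least 0.5. It ranged from 0 to 3, with 3 and 2 without homozygous replicates 1 and 2, and 0 without wildtype replicates 2, 4, 5 and 6, heterozygous replicates 1 to 5 and homozygous replicate 4.

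For lists in homozygous against wildtype (4), the number was 9 with the replicate block, 2 with the 75th percentile covariate, 1 with an estimated correlation and 2 with fry, and 3 to 6 with 1 array left out. In heterozygous against wildtype (3), it was 5 with the replicate block, 0 with the 75th percentile and 1 with the hypoxia covariate, 1 without the 2 arrays that stand apart, and 0 with an estimated correlation and with fry. It ranged from 2 to 5, with 5 without heterozygous replicate 2 or 4. Of 14 pairs of arrays with the same replicate number, 7 had a correlation over 0.1. Their median was 0.0611, against -0.0282 for pairs with different numbers. Of 16 arrays with a possible partner, 4 correlated best with their own number, so the replicate block has only weak support as a pairing. Genes near the floor of the arrays, such as Olfr130, limit what a small change there can show. Not run were an Xist covariate (no probe set is named Xist), another Insm1 probe set (there is 1) and a fit of only the groups compared for allele number and midpoint, which use all groups.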

Other observations

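The tests of array scale, ventral tissue, handling and of gene length as the whole change, and the exact tests of list means, were chosen only after the results were seen.

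The mean of the basal progenitor list per embryo was lower in homozygous embryos, at 5.61 ± 0.06 (SD, n = 4) against 5.84 ± 0.10 (SD, n = 8) in wildtype. The two-sided exact permutation test gave p = 0.00404, the smallest possible (adjusted over 17 lists, 0.0229), and the same values for cortical neurons and Cajal-Retzius neurons. The p53 target list had a mean difference of -0.12 (exact p = 0.0121, adjusted 0.0515), and the hypoxia list of 0.49 (exact p = 0.0566, adjusted 0.16). These tests ask whether a list moved, not whether it moved more than other genes.

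The balance of lower and higher calls in homozygous embryos changed with the scale of the arrays. The share of lower calls was 89.4% as deposited, 46.8% after quantile normalization and 42.8% with the 75th percentile of each array as a covariate. It dropped mainly because higher calls rose, from 10 to 84 and 99, while lower calls went from 84 to 74 in both, and a correction of scale sets this balance in part by its construction. Whether array scale accounts for the excess cannot be told apart from an effect of genotype; the 94 genes kept their direction in each of these settings. The median change of genes with a mean over 4 was -0.09 as deposited and -0.02 under either correction.

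The lower level of cortical neuron genes was weighed against array scale, dissection and handling, and gene length. With the 75th percentile as covariate the list kept 83.1% of its median change, with the ventral list 98.6% and with the hypoxia list 96.1%. Its camera call with the preset correlation held each time. With an estimated correlation the camera call was lost in all 3 (adjusted p = 0.0707, 0.089 and 0.107), as it was without a covariate (adjusted p = 0.077). The share kept with the 75th percentile argues against array scale as the whole cause. The other covariates cannot decide on dissection or handling. The hypoxia list mainly set apart homozygous replicate 2 (4.64) and heterozygous replicate 6 (4.62), so it is a weak measure of handling. The exact permutation test of the list mean minus the mean of genes matched on length and level gave p = 0.00404 (difference -0.28), which argues against length and level as the whole of it. As a part they cannot be told apart from genotype: the median difference from matched genes was -0.18, 56.9% of the list change. That lies between the bounds set beforehand, because the matched genes were lower too (median -0.09). On means per embryo the difference (-0.28, against a change of the list mean of -0.36) was a larger part. Fewer neurons, younger embryos or lower expression per neuron remain open and untested. The ventral list had a low median level (1.88), so as a covariate it is a weak measure of dissection.

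Genes next to Insm1 on chromosome 2 were tested for alleles carried along with the knockout. Within 10 Mb 1 of 139 genes was called, Pak7, or 0.719% against 0.604% elsewhere (Fisher's exact p = 0.571, adjusted 0.941 over 18 tests). Within 30 Mb it was 6 of 474 (Fisher's exact p = 0.0673, adjusted 0.303), among them Plcb1 and Sema6d. At an unadjusted p under 0.001 it was 14 of 474, or 2.95% against 1.37% elsewhere (Fisher's exact p = 0.00879, adjusted 0.158). None of the 18 tests passed after adjustment, and a linked allele may still account for genes there.

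Whether heterozygous embryos move the way of homozygous embryos was tested with the wildtype arrays split between the comparisons. Over 70 splits, 89.4% of 100 picked genes moved the same way. Among 100 relabellings of the heterozygous and wildtype arrays, 2 gave as large a share, the real one included, with a highest other of 90 and a median of 54. Each relabelling used only 1 split, while the real share is a mean over 70, so the rank is approximate. The share was 83.0% without heterozygous replicate 6 and 78.9% after quantile normalization, where 4 of 100 relabellings were as large. The shares of 89.4% and 78.9% ranked high but lay within the range of the relabellings (highest 90, and 86 after quantile normalization). The share without heterozygous replicate 6 was not ranked. The share of 89.4% met the bound set beforehand for a partial effect. By lying within that range it also met the bound set against it. A partial effect of 1 lost allele is possible but not settled by this, and no single gene passed.

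Other splits of the embryos into groups of the same sizes were compared with the real one, 100 each with the real one included. For homozygous against wildtype, 1 split gave as many as 94 genes (highest other 1), and for allele number 1 gave as many as 113 (highest other 2). In each only the real split reached its count, which argues against chance. The splits treat embryos as independent, and the labels do not say whether they came from separate litters. For homozygous against heterozygous, 3 splits gave as many as 5 genes. This is fewer than 5 of 100, the bound set beforehand against chance. By itself the rank does not exclude chance, since 11 of the other splits gave calls and the highest other gave 71 genes. That split exchanged heterozygous replicate 6 and homozygous replicate 4, and so put both arrays with a high hypoxia list mean in 1 group; a structure of the samples other than genotype was not tested further. For departure from the midpoint, 5 splits gave at least 1 gene (highest other 38), and chance cannot be excluded. For heterozygous against wildtype the real count was 0, which all 100 splits reach by construction (highest other 1), so the splits say nothing about it. For the number of lists shifted in homozygous against wildtype, 27 splits gave at least 4 (highest other 7). In heterozygous against wildtype 54 gave at least 3 (highest other 11). Chance cannot be excluded for either number. At least 1 list was called in 82 and 85 of the other splits. A camera call with the preset correlation is therefore weak evidence by itself.

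The 6577 probe sets without a place in the probe table were tested separately for homozygous against wildtype. limma called 0 of them, and 482 had an unadjusted p under 0.05.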
